A study of Mus musculus with 16 samples.

How the data were processed

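Gene expression was measured on 16 two-colour Agilent whole-genome mouse arrays, 1 per sorted sample, at postnatal day 1. GABAergic cells carrying GAD67-eGFP were dissociated and sorted by fluorescence from whole brain (4 arrays) and from olfactory bulb, cortex, striatum and cerebellum (3 arrays each). Per the labels, mRNA was isolated on magnetic beads, amplified by global PCR, and 250 ng of cDNA was labelled with Cy5 for the sorted cells and with Cy3 for a common total brain reference amplified the same way. The reference came from 4 mice. The labels give 4 mice dissected for whole-brain samples and 6 for regional samples. They do not say whether samples of different regions share animals. The labels of the reference channel name Cy3 but call it red, which conflicts with the usual colour of that dye; the direction of the ratios rests on the dye names, Cy5 for sorted cells and Cy3 for reference, which all labels give alike. The dyes were not swapped.

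The deposited scanner files hold, per the file headers, mean spot intensity and median local background intensity in both channels, quantified by Agilent Feature Extraction 8.1.1.1 without background subtraction. They also hold, per the file headers, a log10 ratio of sorted cells over reference that the authors obtained from the same software after background subtraction, spatial detrending and dye normalization. The deposited value table equals this log10 ratio to within 0.005 for all 43790 features on all 16 arrays, which settles its scale and direction. It was not centred further: its median per column ran from 0 to 0.0334 on the log10 scale. A line with a missing field was left out, which concerned 1 spot.

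From the mean and background intensities, log2 ratios of sorted cells to reference were computed with limma 3.58.1 in R 4.3.3, with tables handled by the R package data.table (version 1.17.8) and figures drawn by matplotlib 3.10.9. Background was corrected by the normexp method with an offset of 50, which shrinks ratios of dim spots towards 0. Ratios were normalized by loess within each array, with controls and spots marked by the scanner software given weight 0, and were not scaled between arrays. The arrays held 41534 spots that are not controls, or 41174 probes, whose spots were averaged. Probes took gene symbols from a RefSeq table, by accession for 21445 probes, by symbol for 5431 and by synonym for 4631, while 9667 kept the name given by the array. Each gene was represented by its brightest probe, giving 28657 genes. Genes were kept if well above background in the sorted channel on at least 3 arrays or in the reference channel on at least 8, which left 27264 and removed 1393. Signal over background limits what dim genes can show, and the number of arrays limits the precision. For a gene well above background on none of the arrays of its dimmer side, the fold is given as a bound, with the dim signals raised to the lowest signal on the array that was well above background.

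All 16 arrays were fitted with 5 group means by limma's lmFit and eBayes, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The comparisons were each group against the reference, each region against the mean of the other 3, whole brain against the mean of the 4 regions, and a moderated F test among regions. SE values are those of limma. After the results were seen, each difference between groups was also divided between the sorted-cell and the reference channel, from loess-normalized signals brought to the same distribution of average intensity on all arrays. Gene lists were fixed before the data were examined. The 26 lists cover GABA synthesis and transport, forebrain GABAergic transcription factors, medial and caudal ganglionic eminence interneurons, striatal projection neurons, olfactory bulb interneurons, cerebellar GABAergic neurons, the cerebellar granule cell lineage, midbrain and hindbrain patterning, telencephalic patterning, glutamatergic neurons, monoaminergic and cholinergic neurons, astrocytes and radial glia, the oligodendrocyte lineage, microglia, endothelial and mural cells, erythroid cells, meninges and choroid plexus, proliferation, postmitotic neurons, immediate early and dissociation stress genes, GABA receptors, neuropeptides, axon guidance and migration, housekeeping and sex-linked genes. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 260 tests (26 lists in 10 comparisons), and again with an estimated correlation and with fry, which tests whether the genes of a list move one way and does not compare them with other genes.

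Genes were named by a rule fixed before the data were examined. For whole brain against the reference and each region against the others, the rule takes the 10 highest and 10 lowest log2 differences among called genes whose every array shows the direction and whose name is a gene symbol. For the other comparisons it takes 5 each way. It also allows any measured member of the lists. Some genes that the rule names are not reported.

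Alternatives planned before the data were examined were no background correction, the scanner's log ratio, the value table, median centring in place of loess, scaling of log ratios between arrays, no filter and a stricter filter, the mean of a gene's probes, eBayes with trend and robust, array weights, only the groups compared in the fit, leaving out each array in turn, a 2-fold threshold, and replicate number as a block. The scaling between arrays divided the log ratios of each array by their median, so it did not bring the arrays to equal spread. With it, group medians of 0.032 to 0.087 became 0.044 to 0.053. All whole-brain arrays were scanned in 1 batch and all regional arrays in another, so a block for scan was not fitted: it cannot be told apart from whole brain, and the regional comparisons lie within 1 batch. The pipeline was tested on simulated data of 27264 genes. Of 67 genes simulated with a log2 change of 0.5, 77.6% were recovered in striatum against the other regions and 98.5% in whole brain against the reference, all genes with a change of 1 or 2 were recovered in these comparisons, and 16 and 11 unchanged genes were called. Of 100 simulated lists without a shift 0 were called. The simulated genes were drawn independently of each other, so this does not cover false calls of lists whose genes move together.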

Results

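Newborn mice of the GAD67-eGFP line, in which green fluorescent protein marks cells that express glutamate decarboxylase 67 and so make the inhibitory transmitter GABA, gave the material at postnatal day 1. Fluorescent cells were sorted from whole brain, with 4 arrays, and from dissected olfactory bulb, cortex, striatum and cerebellum, with 3 arrays each. Each of the 16 arrays compared amplified cDNA of the sorted cells (Cy5) with amplified cDNA of a total brain reference from 4 mice of the same age (Cy3). A positive log2 ratio thus means a higher signal in the sorted cells. The median spot signal ran from 150.9 to 717.5 units in the sorted channel and from 92 to 254 units in the reference channel. Between 78.1% and 96.6% of spots were well above background in the sorted channel, and 72.1% to 90.7% in the reference channel. After filtering, 27264 genes were tested. Arrays of 1 group correlated across genes at Pearson's r from 0.936 to 0.992. Across genes, which are not independent replicates, whole-brain arrays correlated with regional arrays at 0.621 to 0.751, and arrays of different regions at 0.776 to 0.927.

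The comparison of whole-brain GABAergic cells with the total brain reference asked which genes set these cells apart from brain tissue at large. Transcription factors of forebrain GABAergic neurons were higher in the sorted cells, and genes of glutamatergic neurons, astrocytes and postmitotic neurons were lower. Dlx6os1, a noncoding RNA of the Dlx5 and Dlx6 locus, was higher by 3.29 ± 0.06 on the log2 scale (SE, n = 4 arrays), or 9.74-fold (adjusted p = 1.2e-19). Gja1, the astrocytic gap junction protein connexin 43, was at -4.45 ± 0.10, and Igf2, an imprinted growth factor made by meninges and choroid plexus, at -5.22 ± 0.07. Gad1, which encodes glutamate decarboxylase 67 itself, was at -1.51 ± 0.08 in these 4 arrays, so that the gene behind the sort was lower than in unsorted brain, although it was above the reference in every dissected region. Slc32a1, the vesicular GABA transporter, was higher by 1.21 ± 0.07.

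Of the 8 measured forebrain GABAergic transcription factors, 7 were higher, none lower and 1 was not called. Dlx6 was higher by 2.66 ± 0.07, Dlx1 by 1.71 ± 0.06 and Dlx5 by 1.46 ± 0.07, all homeobox regulators of GABAergic fate in the ventral forebrain. The list as a whole was higher (camera adjusted p = 0.00808; adjusted p = 0.225 with an estimated correlation). The glutamatergic neuron list moved the other way, with 0 of 14 genes higher and 11 lower (camera adjusted p = 0.000181; adjusted p = 0.171 with an estimated correlation). Neurod6, a transcription factor of pyramidal neurons, was at -2.95 ± 0.08, Tbr1, a factor of deep cortical layers, at -2.55 ± 0.08, and Slc17a7, the vesicular glutamate transporter, at -2.46 ± 0.14. Of 18 astrocyte and radial glia genes, 3 were higher and 12 lower (camera adjusted p = 0.00383; adjusted p = 0.117 with an estimated correlation), among them Aldoc at -2.56 ± 0.06, while Hes5, a Notch target, was higher by 1.44 ± 0.07. Meninges and choroid plexus genes had 2 higher and 8 lower of 12 (camera adjusted p = 0.0132; adjusted p = 0.234 with an estimated correlation), and endothelial and mural cell genes had 2 higher and 10 lower of 13 (camera adjusted p = 0.0308; adjusted p = 0.407 with an estimated correlation). Ptgds, a prostaglandin synthase of the meninges, was at -3.05 ± 0.07 and Cldn5, a tight junction protein of endothelium, at -1.47 ± 0.09.

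Genes of postmitotic neurons were also lower in the cells sorted from whole brain. Of 15 postmitotic neuron genes, 1 was higher and 13 were lower (camera adjusted p = 2.98e-05; adjusted p = 0.0764 with an estimated correlation), with Gap43, a growth cone protein, at -3.69 ± 0.07, Snap25, of the vesicle fusion machinery, at -2.50 ± 0.05, and Dcx, a microtubule protein of migrating neurons, at -2.19 ± 0.07. The medial ganglionic eminence interneuron list had 3 higher and 11 lower of 14 (camera adjusted p = 0.0118; adjusted p = 0.189 with an estimated correlation). Its members Sst, encoding somatostatin, and Satb1, a chromatin organiser, were at -3.73 ± 0.07 and -2.40 ± 0.06. Of 9 housekeeping genes 0 were higher and 8 lower (camera adjusted p = 0.000616; adjusted p = 0.194 with an estimated correlation), with Actb, the beta actin gene, at -2.13 ± 0.07. Of 15 GABA receptor genes 3 were higher and 10 lower (camera adjusted p = 0.0202; adjusted p = 0.184 with an estimated correlation), with Gabra5 at -2.07 ± 0.06 and Gabbr2 at -2.15 ± 0.09. All 4 genes of GABA synthesis and transport were called, 1 higher and 3 lower, and the list was not (camera adjusted p = 0.411). Its member Gad2 was at -0.28 ± 0.07, and of the 2 Gad2 probes 1 had the opposite sign. Gad2 was not called with scaling between arrays (-0.17, adjusted p = 0.412), stood at 0.20 with median centring (not called, adjusted p = 0.057) and turned to 0.55 with the mean of its probes. Counts adjusted over the list alone were the same for these 10 lists.

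By the rule for named genes, which takes the largest differences among called genes with a symbol whose every array shows the direction, the others named as higher in whole-brain cells were Agrn, encoding the synaptic organiser agrin, at 3.12, Rplp2, of the ribosomal stalk, at 3.11, Lce1h, a late cornified envelope gene, at 3.11, Ramp2, a receptor partner, at 3.01 (saturated signal on 2 of the 4 arrays), Rps12, a ribosomal protein gene, at 3.00, Apex2, a DNA repair nuclease, at 2.94, Romo1, a small mitochondrial protein, at 2.92, Cops9, a COP9 signalosome subunit, at 2.91 and Rab34, a small GTPase, at 2.84. Only 1 of the 3 probes for Agrn and 1 of 2 for Rplp2, Ramp2 and Apex2 had a positive ratio, as had 2 of 3 for Rab34, while 3 of 4 for Myt1l had a negative one. Among 8599 genes with 2 or more probes, 248 had probes of opposite sign, both beyond 2-fold. Probes of Mapre1 ran from -4.84 to -0.91. Named as lower, beside Igf2 and Gja1, were Cwc22, a splicing factor, at -5.34, Mapre1, a microtubule end-binding protein, at -4.84, Cyria at -4.61, Snhg11 at -4.59, Myt1l, a neuronal transcription factor, at -4.57, Enc1 at -4.40, Mmab, of cobalamin metabolism, at -4.23, and Apod, a lipid carrier, at -4.18. In all, 21729 of 27264 genes were called, 12318 higher and 9411 lower, and 6091 of them by at least 2-fold (2355 higher, 3736 lower). The scanner's own log ratio raised the median of all genes in this comparison by 0.166 on the log2 scale, from 0.087 to 0.253. A ratio against the reference leaves out the reference's own spread between preparations and any gene-specific dye effect, since the dyes were not swapped.

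**Figure D1:**
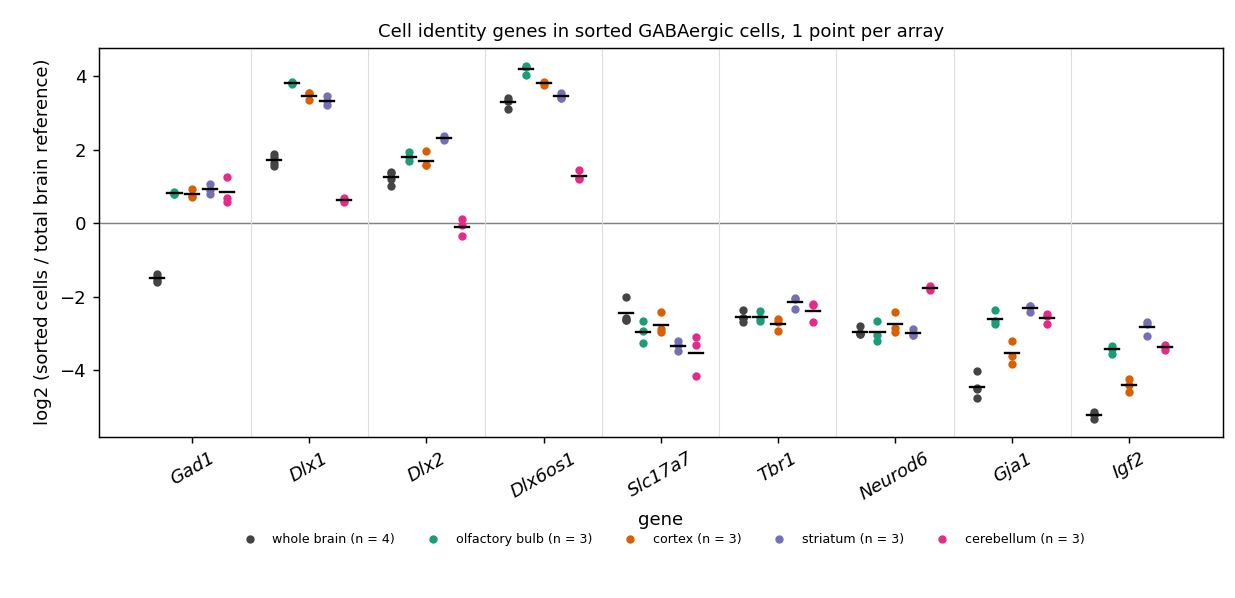
Log2 ratio of sorted cells to the total brain reference for 9 genes, with single arrays as points coloured by group and group means as short black lines. Gad1 lies below 0 in whole brain, with a mean of -1.51, and above 0 in the regions, while Slc17a7, Tbr1, Neurod6, Gja1 and Igf2 lie below 0 in all 5 groups.

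The genes of GABA synthesis and transport were higher than in the reference in the 3 forebrain regions, and the list was not called in cerebellum. All 4 were called higher in olfactory bulb (camera adjusted p = 0.0361; adjusted p = 0.391 with an estimated correlation), in cortex (camera adjusted p = 0.0348; adjusted p = 0.39 with an estimated correlation) and in striatum (camera adjusted p = 0.0148; adjusted p = 0.332 with an estimated correlation). In cerebellum 3 were higher and 1 lower (camera adjusted p = 0.213). Gad1 was higher by 0.81 ± 0.10 in olfactory bulb, 0.79 ± 0.10 in cortex, 0.91 ± 0.10 in striatum and 0.84 ± 0.10 in cerebellum (SE, n = 3 arrays each). Gad2, the second glutamate decarboxylase gene, was higher by 1.89 ± 0.08, 1.82 ± 0.08, 1.78 ± 0.08 and 0.90 ± 0.08 in the same order. Dlx6os1 was the gene with the highest ratio in olfactory bulb (4.19 ± 0.07, 18.3-fold), cortex (3.80 ± 0.07) and striatum (3.46 ± 0.07). Dlx1 was at 3.81 ± 0.07, 3.46 ± 0.07 and 3.33 ± 0.07.

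Glutamatergic neuron genes were lower in the 3 forebrain regions, with 12 of 14 lower in each, and with 1 higher in olfactory bulb (camera adjusted p = 2.69e-06; adjusted p = 0.0956 with an estimated correlation), 0 higher in cortex (7.21e-06 and 0.113) and 1 higher in striatum (3.81e-06 and 0.102). In cerebellum 5 were higher and 8 lower (camera adjusted p = 0.105). Astrocyte and radial glia genes were lower against the reference in all 4 regions, with 14, 13, 13 and 14 of 18 lower in olfactory bulb, cortex, striatum and cerebellum (camera adjusted p = 0.000276, 0.000108, 0.000773 and 0.000951; 0.0775, 0.0764, 0.0801 and 0.081 with an estimated correlation). Gja1 was at -2.60, -3.55, -2.31 and -2.58 in that order. Postmitotic neuron genes had 12, 12, 11 and 11 of 15 lower (camera adjusted p = 0.000283, 0.000123, 4.72e-05 and 0.000164; 0.0868, 0.0801, 0.0775 and 0.0801 with an estimated correlation), with Gap43 at -3.99, -3.98, -3.72 and -3.01. The immediate early and dissociation stress list, transcripts that rise within minutes of stimulation or tissue handling, had 7, 9, 10 and 11 of 13 genes higher. It was called in cortex (camera adjusted p = 0.00484; adjusted p = 0.203 with an estimated correlation), striatum (0.000333 and 0.132) and cerebellum (0.00137 and 0.171), and not in olfactory bulb (0.0766). Fos, the best known of these genes, was higher by 1.62 ± 0.14, 2.49 ± 0.14, 3.09 ± 0.14 and 3.43 ± 0.14.

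Among the other genes named by the rule, Ramp2 was higher in olfactory bulb (3.37), cortex (2.97) and cerebellum (2.81, saturated signal on 1 of 3 arrays), where 1 of its 2 probes had the opposite sign, and Sp8, a zinc finger factor of interneurons, in olfactory bulb (3.34) and striatum (2.92). Tiam2, a Rac exchange factor, reached 3.39 in cortex and 3.38 in striatum, Dusp4, a MAP kinase phosphatase, 3.33 in olfactory bulb, and Fgb, fibrinogen beta, 3.09 in cortex. Pax2, Cnpy1 and Skor1 were higher in cerebellum by 3.17, 2.94 and 2.90. Cwc22 was at -4.14, -4.33, -4.48 and -4.32 in the 4 regions, and Ptgds at -4.19, -4.30, -3.93 and -3.56. Snhg11 was at -4.50, -4.65 and -4.27 in the forebrain regions, Enc1 at -4.20 in olfactory bulb and -3.73 in cerebellum, and Sst at -4.26 in olfactory bulb. Igf2 was at -4.41 in cortex, Chrna4, a nicotinic receptor subunit, at -3.67 in striatum, and Spp1, osteopontin, at -3.54 in cerebellum. Dync1i1, of the dynein motor, was at -3.98 in cerebellum, with 1 of its 2 probes of opposite sign. Against the reference, 18521 genes were called in olfactory bulb (10007 higher), 18949 in cortex (10355 higher), 18418 in striatum (9854 higher) and 20724 in cerebellum (11671 higher). With a difference of at least 2-fold the counts were 3936, 3792, 2572 and 4542.

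The regions were then compared with each other as ratios to the common reference. A difference between such ratios can lie in the sorted-cell channel or in the reference channel. Of the genes called with a 2-fold difference, less of the difference lay in the sorted-cell channel than in the reference channel for 16 of 164 in olfactory bulb, 6 of 42 in cortex, 15 of 92 in striatum and 16 of 319 in cerebellum. Of 27264 genes, 15693 (57.6%) differed among the 4 regions by limma's moderated F test, and 1028 of these also had a 2-fold range between the highest and lowest region means. Each region was set against the mean of the other 3, so a gene that differed in cerebellum alone also moved the forebrain comparisons. With cerebellum left out of that mean, which was done after the results were seen, less than 50% of the difference was left for 3 of 35 named genes in olfactory bulb, 6 of 27 in cortex and 7 of 31 in striatum. All regional arrays were scanned in 1 batch. A fit of these 12 arrays alone called 16484 genes.

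Olfactory bulb GABAergic cells stood apart from the other 3 regions by genes of olfactory bulb interneurons. Of 13 such genes 10 were higher and 2 lower, and the list was called with the preset correlation (camera adjusted p = 3.82e-08) and with an estimated correlation (adjusted p = 0.0411). Calb2, encoding the calcium-binding protein calretinin, was higher by 1.92 ± 0.08 (SE, n = 3 against 9 arrays; 3.79-fold, adjusted p = 6.61e-12), and Etv1, a transcription factor of dopaminergic bulb interneurons, by 1.74 ± 0.08. Without cerebellum Calb2 was at 2.10 and Etv1 at 0.99. Kitl, the ligand of the Kit receptor, was the highest at 2.20 ± 0.15, or 4.58-fold (adjusted p = 2.67e-09). Zfhx3, a homeobox factor, and Foxp1, a forkhead factor of striatal neurons, were the lowest at -2.25 ± 0.07 and -2.06 ± 0.08.

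Within the olfactory bulb interneuron list Tshz1 was higher by 1.42 ± 0.07, Pbx3 by 1.40 ± 0.08 and Sp8 by 1.21 ± 0.10, while Tpbg was at -0.73 ± 0.09 (0.79 for Tshz1, 0.98 for Pbx3, 0.51 for Sp8 and -0.36 for Tpbg without cerebellum). Forebrain GABAergic transcription factors had 6 of 8 higher and 1 lower (camera adjusted p = 0.000413; adjusted p = 0.133 with an estimated correlation), with Dlx1 higher by 1.34 ± 0.08. Without cerebellum the list median fell from 0.69 to 0.12 and Dlx1 to 0.42. The striatal projection neuron list had 2 of 21 higher and 12 lower, or 3 and 13 adjusted over the list alone (camera adjusted p = 4.72e-05; adjusted p = 0.081 with an estimated correlation). Its member Ebf1 was at -1.22 ± 0.14, and Meis2, which bulb interneurons also express, was higher by 0.95 ± 0.08. Microglial genes were lower in olfactory bulb, with 0 of 14 higher and 9 lower, or 11 lower adjusted over the list alone (camera adjusted p = 2.12e-05; adjusted p = 0.0542 with an estimated correlation), among them Tyrobp at -1.04 ± 0.07 and P2ry12 at -0.83 ± 0.10. Proliferation genes had 0 of 18 higher and 10 lower, or 11 lower adjusted over the list alone (camera adjusted p = 0.000811; adjusted p = 0.14 with an estimated correlation), with Birc5, encoding survivin, at -1.07 ± 0.14. The immediate early list had 1 of 13 higher and 10 lower (camera adjusted p = 3.81e-06; adjusted p = 0.0801 with an estimated correlation), with Fos at -1.38 ± 0.17. Glutamatergic neuron genes had 0 of 14 higher and 9 lower (camera adjusted p = 0.000136; adjusted p = 0.164 with an estimated correlation), with a median of -0.43, or -0.10 without cerebellum.

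Further genes named in olfactory bulb were Dusp4 at 2.18, Pcbp3, an RNA-binding protein, at 2.04, Gng4, a G protein subunit, at 1.92, Epb41l3 at 1.89, Gas2l3 at 1.75, Fgfr2, a fibroblast growth factor receptor, at 1.74 and Sdk2, a cell adhesion protein, at 1.64 (3 of 4 probes of that sign; 0.45 in the sorted-cell channel). Lower were Sst at -1.97, Nkx2-1, the patterning factor of the medial ganglionic eminence, at -1.75, Cadm1 and Chl1, both adhesion molecules, at -1.73 and -1.61, Mela at -1.56 (0.24 in the sorted-cell channel, so that the difference lay in the reference channel), Rph3a, a synaptic vesicle protein, at -1.51, Nyap1 at -1.50 and Scube1 at -1.50. On the whole 8128 genes were called, 3767 higher and 4361 lower, and 164 by at least 2-fold (87 higher, 77 lower). The fit of the 12 regional arrays alone called 8715. With median centring in place of loess the split turned to 5620 higher and 3669 lower, that is 60.5% higher against 46.3%.

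Cortical GABAergic cells differed from the other regions in fewer genes. Zic1, Zic2 and Zic5, zinc finger factors of the cerebellar and septal lineages, were lower in cortex, at -1.89 ± 0.09 (3.7-fold, adjusted p = 2.29e-10), -1.75 ± 0.09 and -1.64 ± 0.07 (SE, n = 3 against 9 arrays). Without cerebellum these 3 genes were at -1.27, -0.95 and -0.87. Astrocyte and radial glia genes were lower, with 0 of 18 higher and 10 lower, or 11 lower adjusted over the list alone. This list was called with the preset correlation (camera adjusted p = 4.64e-08) and with an estimated correlation (adjusted p = 0.0411). Slc1a3, a glial glutamate transporter, was at -1.49 ± 0.08, Fabp7, a lipid-binding protein of radial glia, at -1.12 ± 0.08 and Gja1 at -1.05 ± 0.13.

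Genes of the striatal projection neuron list were higher in cortex, 9 of 21 with 0 lower, or 14 higher adjusted over the list alone (camera adjusted p = 5.78e-08; adjusted p = 0.0542 with an estimated correlation). Of these, Bcl11b, which deep-layer cortical neurons also express, was higher by 0.85 ± 0.07, and Pde10a, a phosphodiesterase of striatal neurons, by 0.53 ± 0.08. Both stood higher in striatum, and only 2 of the 9 were highest in cortex. Without cerebellum Bcl11b was at 0.09. The forebrain GABAergic transcription factors had 5 of 8 higher and 0 lower (camera adjusted p = 0.000276; adjusted p = 0.127 with an estimated correlation). However, 0 of the 5 were highest in cortex, and the median went from 0.38 to -0.16 without cerebellum. Cerebellar GABAergic neuron genes had 0 of 19 higher and 8 lower, or 9 lower adjusted over the list alone (camera adjusted p = 5.63e-05; adjusted p = 0.0673 with an estimated correlation), with Lhx5 at -1.46 ± 0.12 and Pax2 at -1.20 ± 0.11. These 2 values came mainly from cerebellum, without which they were -0.01 and -0.20, and the list median went from -0.18 to 0.03. Proliferation genes had 0 of 18 higher and 8 lower, or 11 lower adjusted over the list alone (camera adjusted p = 2.12e-05; adjusted p = 0.0801 with an estimated correlation), with Mcm2, a replication licensing factor, at -0.63 ± 0.09. Oligodendrocyte lineage genes had 0 of 11 higher and 5 lower, or 7 lower adjusted over the list alone (camera adjusted p = 0.000991; adjusted p = 0.0764 with an estimated correlation). Their median went from -0.29 to -0.14 without cerebellum.

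By the same rule, the ratio in cortex was higher for Lyz1 at 1.60 ± 0.19 and Lyz2 at 1.20 ± 0.24, lysozyme genes of myeloid cells, and the second Lyz2 probe had the opposite sign. Their sorted-cell signals were not higher in cortex: the difference was -0.004 for Lyz1 and -1.33 for Lyz2, against -1.61 and -2.53 in the reference channel. Aldh1a1, a retinoic acid synthesising enzyme, was higher by 0.93, Pomgnt1, a glycosyltransferase, by 0.74, Tmem204 by 0.73 and Napsa, an aspartic protease, by 0.72. B3gat3, Ccdc116, Tesmin and Iba57 were higher by 0.82, 0.80, 0.80 and 0.71 with the probe used, and of their probes 2 of 4, 1 of 2, 1 of 2 and 1 of 2 had that sign, and B3gat3 was not called with the mean of its probes (0.14). Lower were Ptprk, a receptor phosphatase, at -1.63 (-0.79 without cerebellum), Plagl1, an imprinted zinc finger gene, at -1.48, Dbi, an acyl-CoA-binding protein of glia, at -1.30, Lamb1, a laminin chain, at -1.22 (-0.59 without cerebellum), Apod at -1.21 and Igf2 at -1.19. In total 2858 genes were called, 1213 higher and 1645 lower, and 42 by at least 2-fold (13 higher, 29 lower). The fit of the 12 regional arrays alone called 3291, array weights raised the count to 6185, and leaving out cortex replicate 1, 2 or 3 lowered it to 1149, 1840 or 1260.

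Striatal GABAergic cells had higher levels of striatal projection neuron genes and of some medial ganglionic eminence interneuron genes, and also of several glial and microglial genes. Ttr, encoding transthyretin and abundant in choroid plexus, stood highest at 3.42 ± 0.15, or 10.7-fold (SE, n = 3 against 9 arrays; adjusted p = 3.58e-11). Nkx2-1 was higher by 2.08 ± 0.12, Bcl11b, a zinc finger factor of striatal projection neurons, by 1.76 ± 0.07, Foxp1 by 1.72 ± 0.08 and Isl1, a factor of striatonigral neurons, by 1.43 ± 0.10. Lhx5, a LIM homeobox factor, was lowest at -1.92 ± 0.12, but at -0.53 without cerebellum. A hand-written list of short transcripts lay above a list of long ones by 0.261 in striatum, against -0.123 in olfactory bulb, -0.102 in cortex and 0.077 in cerebellum.

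Of the 21 striatal projection neuron genes 11 were higher and 1 lower (camera adjusted p = 3.81e-06; adjusted p = 0.0764 with an estimated correlation). Penk, encoding proenkephalin, was higher by 0.88 ± 0.09, but was not called with log ratios scaled between arrays (0.30, adjusted p = 0.234). The medial ganglionic eminence interneuron list had 5 of 14 higher and 3 lower, or 5 and 4 adjusted over the list alone (camera adjusted p = 0.012; adjusted p = 0.189 with an estimated correlation), with Npy, a neuropeptide, higher by 1.41 ± 0.10, Lhx8, a cholinergic fate factor, by 1.23 ± 0.10, and Lhx6, an interneuron factor, by 1.07 ± 0.08. Of these 5 higher genes 4 were highest in striatum, but the list median went from 0.14 to -0.01 without cerebellum. The forebrain GABAergic transcription factors had 5 of 8 higher and 0 lower, or 6 higher adjusted over the list alone (camera adjusted p = 4.76e-05; adjusted p = 0.0956 with an estimated correlation), with Dlx2 higher by 1.18 ± 0.10. Only 2 of the 5 were highest in striatum, and without cerebellum the median fell from 0.58 to 0.04 and Dlx2 to 0.56. The telencephalic patterning list had 4 of 7 higher and 0 lower, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.00438; adjusted p = 0.0775 with an estimated correlation).

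Microglial genes were higher in striatum, 8 of 14 with 1 lower (camera adjusted p = 0.000123; adjusted p = 0.0764 with an estimated correlation), with Ctss, a lysosomal protease, higher by 0.99 ± 0.14 and Fcer1g, an immune receptor chain, by 0.84 ± 0.08. The list was also called higher in cerebellum, 6 with 1 lower, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.0381; adjusted p = 0.202 with an estimated correlation). A further list of 20 microglia genes had 3 higher and 4 lower in striatum, with a median of -0.022. Of 18 astrocyte and radial glia genes 10 were higher and 3 lower (camera adjusted p = 0.000553; adjusted p = 0.0801 with an estimated correlation), but with log ratios scaled between arrays 4 were higher and 4 lower. Hes1, a Notch target of radial glia, and Vim, an intermediate filament gene, were higher by 1.14 ± 0.09 and 0.86 ± 0.08. Of 13 endothelial and mural cell genes 5 were higher and 3 lower, or 6 and 3 adjusted over the list alone (camera adjusted p = 0.0866). With log ratios scaled between arrays 2 were higher and 6 lower. That scaling divides each array by its median log ratio, so it shifts lists with low ratios in all regions. Its counts for such lists cannot decide. Proliferation genes had 9 of 18 higher and 2 lower (camera adjusted p = 0.000612; adjusted p = 0.133 with an estimated correlation), with Cdk1, the mitotic kinase, higher by 0.71 ± 0.10. The immediate early list had 7 of 13 higher and 1 lower (camera adjusted p = 0.00204; adjusted p = 0.182 with an estimated correlation), with Jun higher by 1.09 ± 0.09. Only 3 of the 7 were highest in striatum, and the median went from 0.23 to 0.41 without cerebellum. Of 9 housekeeping genes 3 were higher and 0 lower (camera adjusted p = 0.0184; adjusted p = 0.364 with an estimated correlation), but 2 were higher and 3 lower with log ratios scaled between arrays.

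Other named genes were higher in striatum by 2.10 for Sulf1, a heparan sulfatase, 1.47 for Igfbp7, 1.46 for Foxj1, a regulator of motile cilia found in ependymal cells, 1.44 for Cadm1 and 1.42 for Slco1c1, a thyroid hormone transporter of endothelium and choroid plexus. Lower were Asic4 at -1.43, Prdm8 at -1.16, Skor1 at -1.12, Aqp5, a water channel, at -1.09 (0.01 in the sorted-cell channel), Kcnj6, a potassium channel, at -0.97, Ece1 at -0.96 (-0.06 in the sorted-cell channel), Ephb1, an ephrin receptor, at -0.93, Sh3gl2, of synaptic endocytosis, at -0.88 and Stambpl1 at -0.87 (not called with log ratios scaled between arrays, at -0.47). Without cerebellum Asic4 was at -0.47, Prdm8 at -0.29, Skor1 at -0.19, Kcnj6 at -0.38 and Ephb1 at -0.41. Altogether 8243 genes were called, 3695 higher and 4548 lower, and 92 by at least 2-fold (63 higher, 29 lower). The fit of the 12 regional arrays alone called 8786, array weights raised the count to 13181, and it fell to 5379 without striatum replicate 1 and to 5453 without striatum replicate 2.

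Cerebellar GABAergic cells differed most from the other regions. Genes of cerebellar GABAergic neurons, of the midbrain and hindbrain and of cerebellar granule cells were higher, and genes of the Dlx family were lower. Lhx5, which marks early cerebellar GABAergic neurons, was higher by 4.36 ± 0.12, or 20.5-fold (SE, n = 3 against 9 arrays; adjusted p = 6.78e-15). Pax2, the paired box factor of cerebellar interneuron precursors, was higher by 3.07 ± 0.11, or 8.42-fold. Dlx1 was lowest at -2.90 ± 0.08.

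Of 19 cerebellar GABAergic neuron genes 14 were higher and 1 lower, or 17 and 1 adjusted over the list alone, with a call under the preset correlation (camera adjusted p = 7.86e-07) and under an estimated correlation (adjusted p = 0.0411). Tfap2b, an AP-2 factor, was higher by 2.44 ± 0.09 and En2, the engrailed factor of the cerebellum, by 1.28 ± 0.08. Midbrain and hindbrain patterning genes had 15 of 23 higher and 1 lower, also with both calls (camera adjusted p = 2.69e-06; adjusted p = 0.0467 with an estimated correlation). In this list Otx2, a factor of the midbrain and of the posterior cerebellum, was higher by 2.85 ± 0.12, Gata3 by 2.04 ± 0.08, and Pax3, not above background on any of the 9 arrays of the other regions, was at least 4.77-fold higher. Cerebellar granule cell lineage genes had 9 of 12 higher and 1 lower (camera adjusted p = 8.96e-06; adjusted p = 0.06 with an estimated correlation), with Zic2 higher by 2.71 ± 0.09, Zic1 by 2.27 ± 0.09 and Atoh1, the granule cell fate factor, by 0.69 ± 0.10. The glutamatergic neuron list had 8 of 14 higher and 2 lower (camera adjusted p = 9.4e-05; adjusted p = 0.152 with an estimated correlation). Its higher members Neurod2 (2.79 ± 0.09), Nrn1 (1.87 ± 0.08) and Neurod1 (1.49 ± 0.11) are expressed in granule cells too. Tbr1 (0.10 ± 0.11) was not called, but was called at 0.22 with array weights and at 1.79 with log ratios scaled between arrays. That scaling divides by median log ratios that differed between regions (0.077 in cerebellum, 0.033 in striatum). It can thus set regions apart in a gene with low ratios in all of them, and the 1.79 does not show a higher level in cerebellum.

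The forebrain GABAergic transcription factors had 2 of 8 higher and 6 lower in cerebellum, with a median of -2.02 (camera adjusted p = 1.63e-06; adjusted p = 0.0764 with an estimated correlation). Dlx5 and Sp8 were at -2.08 ± 0.10 and -2.27 ± 0.10. The olfactory bulb interneuron list had 1 of 13 higher and 7 lower, called under both correlations (camera adjusted p = 4.37e-07; adjusted p = 0.0411 with an estimated correlation), with Etv1 at -2.57 ± 0.08 and Tshz1 at -2.15 ± 0.07. The striatal projection neuron list had 2 of 21 higher and 8 lower (camera adjusted p = 0.00219; adjusted p = 0.169 with an estimated correlation). Oligodendrocyte lineage genes had 6 of 11 higher and 0 lower, or 8 higher adjusted over the list alone (camera adjusted p = 0.00155; adjusted p = 0.0764 with an estimated correlation), with Pdgfra, the receptor of oligodendrocyte precursors, higher by 1.09 ± 0.07. Proliferation genes had 10 of 18 higher and 0 lower (camera adjusted p = 0.0142; adjusted p = 0.234 with an estimated correlation), with Mcm3 higher by 0.79 ± 0.08.

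Further genes named as higher in cerebellum were Ebf3, a transcription factor, at 3.89, Cnpy1 at 3.10, Asic4, of the acid-sensing ion channel family, at 3.03, Skor1, a corepressor, at 2.84 and Ptprk at 2.78. Named as lower were Dlx6os1 at -2.54, Spp1 at -2.47 (-0.91 in the sorted-cell channel), Bcl11b at -2.30, Tiam2 at -2.27 and Sox2, a progenitor factor, at -2.11. The test called 11051 genes, 6549 higher and 4502 lower, and 319 by at least 2-fold (180 higher, 139 lower). With median centring in place of loess the split turned to 5434 higher and 5315 lower, that is 50.6% higher against 59.3%. With the scanner's log ratio 53% were higher. The fit of the 12 regional arrays alone called 11621, and array weights raised the count to 16913.

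**Figure D2:**
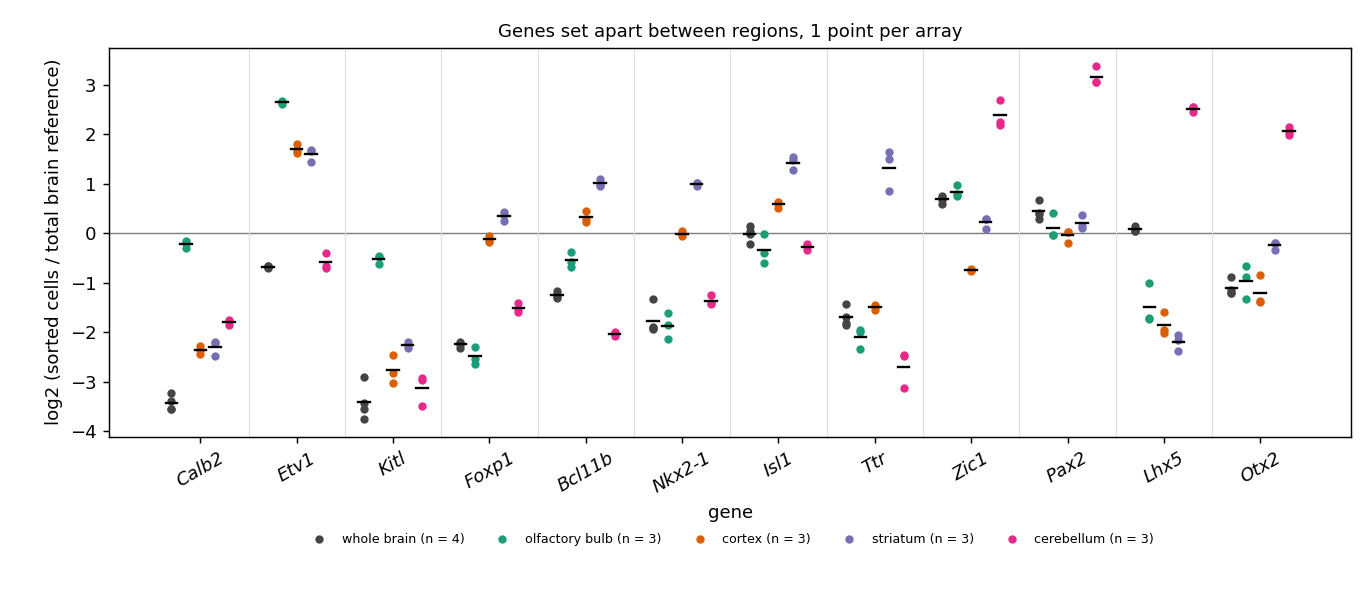
Log2 ratio of sorted cells to the total brain reference for 12 genes that differed between regions, with single arrays as points coloured by group and group means as short black lines. Calb2, Etv1 and Kitl are highest in olfactory bulb, Foxp1, Bcl11b, Nkx2-1, Isl1 and Ttr in striatum, and Zic1, Pax2, Lhx5 and Otx2 in cerebellum.

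**Figure D3:**
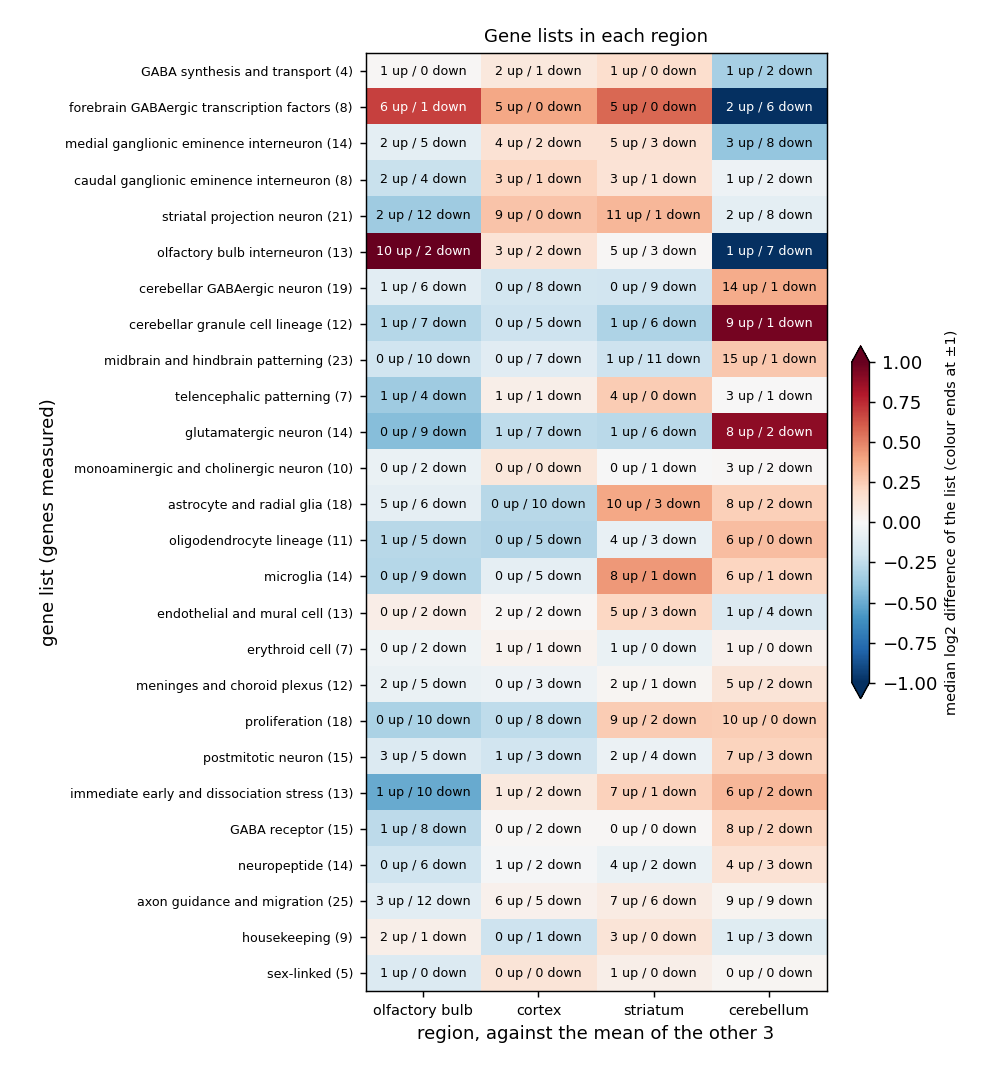
Median log2 difference of each of the 26 gene lists in each region against the mean of the other 3 regions, as colour, with the number of members called higher and lower written in each cell. The olfactory bulb interneuron list has a median of 1.04 in olfactory bulb, and the forebrain GABAergic transcription factor list a median of -2.02 in cerebellum.

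Whole-brain GABAergic cells were last set against the mean of the 4 regions. All whole-brain arrays came from other mice and were scanned in another batch than all regional arrays, so that tissue, preparation and scan cannot be told apart here. Romo1 was higher in whole brain by 4.03 ± 0.08, or 16.4-fold (SE, n = 4 against 12 arrays; adjusted p = 6.61e-18), and the ribosomal protein genes Rps4x and Rps12 by 3.97 ± 0.14 and 3.56 ± 0.07. Mapre1 was lower, at -4.33 ± 0.08, as were Sox11, a transcription factor of immature neurons, at -3.89 ± 0.08 and Nfib, a nuclear factor I gene, at -3.76 ± 0.10. All probes of these genes had this sign but differed in size. They ran from -4.33 to -0.15 for Mapre1, -3.89 to -0.97 for Sox11 and -5.10 to -1.07 for Nfib.

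Genes of GABA synthesis and transport had 1 of 4 higher and 3 lower (camera adjusted p = 0.0494; adjusted p = 0.412 with an estimated correlation), with Gad1 at -2.34 ± 0.10 and Gad2 at -1.87 ± 0.08 (1 of 2 probes of that sign). The olfactory bulb interneuron list had 3 of 13 higher and 9 lower, or 4 and 9 adjusted over the list alone (camera adjusted p = 0.0212; adjusted p = 0.182 with an estimated correlation), with Etv1 at -2.02 ± 0.07. The immediate early list had 2 of 13 higher and 9 lower, or 2 and 10 adjusted over the list alone (camera adjusted p = 0.0103; adjusted p = 0.234 with an estimated correlation), with Egr1 at -1.48 ± 0.10 and Fos at -1.07 ± 0.14. Monoaminergic and cholinergic neuron genes, whose cell bodies lie largely in the brain stem and basal forebrain, had 6 of 10 higher and 0 lower, or 7 higher adjusted over the list alone (camera adjusted p = 0.0348; adjusted p = 0.253 with an estimated correlation). In that list Fev, a factor of serotonergic neurons, was higher by 0.65 ± 0.08 and Slc6a3, the dopamine transporter, by 0.62 ± 0.06. Of the 9 housekeeping genes 3 were higher and 5 lower, or 4 and 5 adjusted over the list alone (camera adjusted p = 0.2), and 6 higher and 2 lower with log ratios scaled between arrays. Actb was at -3.60 ± 0.08 and Tbp, the TATA-binding protein gene, at -1.76 ± 0.08. Dcx was at -2.54 ± 0.08 and Satb1 at -2.12 ± 0.07.

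The other named genes were Cops9, higher by 3.71, Tubb2b, a tubulin gene, higher by 3.64, Samd8 at -3.52 (-0.22 for its other probe) and Peg10, an imprinted gene, at -3.42. Of 8599 genes with 2 or more probes, 79 had probes of opposite sign, both beyond 2-fold. This contrast called 16860 genes, 8534 higher and 8326 lower, and 2673 by at least 2-fold (808 higher, 1865 lower). With median centring 10827 were higher and 7027 lower, that is 60.6% higher against 50.6%.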

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

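The tests of the reference channel, of housekeeping genes, of a lower share of GABAergic cells and of narrower log ratios were chosen after the results were seen; the further gene lists were written down before they were tested, although their members Foxj1, Otx2, Folr1, Ramp2 and Zic5 had already been examined.

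Among 59 genes named in whole-brain comparisons, 5 had 1 of the 4 whole-brain arrays far from the other 3. The cut-off of this rule is set so that chance alone would flag about 1 in 20 genes, a rate that was not measured here. In whole brain 4 the log2 ratio to the reference was -1.30 for Cldn5 (others -1.53 to -1.52), -2.34 for Dcx (others -2.15 to -2.12), -0.40 for Gad2 (others -0.25 to -0.22) and -3.98 for Gap43 (others -3.61 to -3.58). In whole brain 1 it was -2.00 for Slc17a7 (others -2.64 to -2.57).

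Among the named genes, a further 17 were called against the reference in 1 group in the opposite direction to all other 4 groups. For these the difference itself was called and was at least 4-fold, a size that the rule required. Between whole brain and the mean of the 4 regions it was 4.03 for Romo1, 3.97 for Rps4x, 3.64 for Tubb2b, 3.56 for Rps12, -2.34 for Gad1, -3.60 for Actb, -3.76 for Nfib and -3.89 for Sox11. Between cerebellum and the other 3 regions it was 3.89 for Ebf3, 3.03 for Asic4, 2.79 for Neurod2, 2.69 for Prdm8, 2.60 for Zic5, 2.44 for Tfap2b and 2.04 for Gata3. Pcbp3 was higher in olfactory bulb by 2.04 and Ttr in striatum by 3.42.

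Whole-brain arrays differed from the regional arrays in some genes that all cells use, such as Actb, Romo1 and Rps4x, but the housekeeping list was not called (3 of 9 higher, 5 lower; camera adjusted p = 0.2) and ribosomal protein genes went both ways (41 higher, 29 lower). A different reference is argued against, since over 2673 genes with a 2-fold difference the reference channel accounted for 2.8% of it at the median. A hand-written list of 50 short transcripts lay above a list of 48 long ones by 1.502 on the log2 scale (medians 0.98 and -0.52), so unequal recovery of short transcripts may contribute, on both sides, as short minus long was 0.926 in whole brain and -1.01 to -0.717 in the regions against the reference, although respiratory chain genes (median 1.05) moved more than ribosomal protein genes (0.20). Cells of parts not dissected stay open. In the test 3 of 9 housekeeping genes had a 2-fold difference, but such genes cannot show whether those cells were present. Tissue, preparation and scan batch cannot be told apart.

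Microglial genes, and astrocyte genes without scaling between arrays, were higher in the striatal arrays (adjusted p = 0.0764 and 0.0801 with an estimated correlation), the microglial ones also in cerebellum (adjusted p = 0.202 with an estimated correlation), while the endothelial list was not called (5 higher, 3 lower; camera adjusted p = 0.0866). A lower share of GABAergic cells, raising all other types alike, stays open. The microglial median lay 0.704 above the glutamatergic one (two-sided permutation p = 4e-04). However, the comparison included cerebellum, where glutamatergic genes were higher. Without cerebellum the glutamatergic median went from -0.271 to 0.065 and the microglial one from 0.433 to 0.534. The test required a glutamatergic median under 0, so it cannot decide. Choroid plexus and ependymal cells may have been carried over, since a further list of 18 such genes had a median of 0.20, 8 higher and 0 lower, at percentile 100 of 10000 random lists (median 0.206 without the 3 genes examined before). The random lists were matched on signal alone, so the percentile does not allow for genes of a list moving together. Against carry-over, the fixed meninges and choroid plexus list had 2 of 12 higher and 1 lower (median 0.02, camera adjusted p = 0.301). With scaling between arrays it had 2 higher and 6 lower (median -0.49), which cannot decide, as that scaling shifts lists with low ratios. Fluorescence sorting is meant to remove such cells, but how pure the sorted cells were was not tested. Further lists of microglia (3 of 20 higher, 4 lower, median -0.022) and of vascular genes (7 of 20 higher, 7 lower, median -0.089) decided nothing. Narrower log ratios on the striatal arrays stay open. The test used the scaling between arrays, which divides by the median log ratio and does not equalise spread, so it cannot decide. With it the median of 45 glial, microglial and endothelial genes went from 0.234 to 0.031. The microglial list kept 7 higher and 1 lower (median 0.433 before, 0.265 after). Recovery of short transcripts (short minus long 0.261) stays open too, and a difference of the region itself was not tested.

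Granule cell lineage and glutamatergic genes were higher in the cerebellar arrays (adjusted p = 0.06 and 0.152 with an estimated correlation). Granule cell precursors may have been carried over: a further list of 15 granule lineage genes had a median of 0.90, 13 higher and 1 lower, at percentile 100 of 10000 random lists (median 0.802 without the 1 gene examined before). Here too the random lists were matched on signal alone, and the percentile does not allow for genes moving together. Fluorescence sorting is meant to remove such cells, but the purity of the sorted cells was not tested, so this does not decide. Expression of these genes by cerebellar GABAergic cells themselves was not tested and stays open.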

How the results depend on the processing

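All alternatives were planned before the data were examined, and no test here was chosen after the results were seen. Of the 11 counts of called genes, each stayed within 1.5 times under the alternatives except as follows. With a 2-fold threshold they were 6091, 3936, 3792, 2572 and 4542 against the reference (whole brain, olfactory bulb, cortex, striatum, cerebellum), 164, 42, 92 and 319 for each region in that reading order (olfactory bulb, cortex, striatum, cerebellum), 2673 for whole brain against the regions and 1028 among regions, since fewer genes pass. With array weights the counts rose to 6185 in cortex, 13181 in striatum and 16913 in cerebellum, and the cause was not tested. Leaving out 1 array gave 20658 to 21944, 16751 to 18825, 17037 to 19276, 16270 to 18787 and 18906 to 20988 against the reference, 5577 to 8717, 1149 to 3312, 5379 to 8843 and 8949 to 11646 for the regions, 15252 to 17218 for whole brain against the regions and 13813 to 16460 among regions. The cortex count fell to 1149, 1840 and 1260 without cortex replicate 1, 2 and 3, and the striatum count to 5379 and 5453 without striatum replicate 1 and 2. Of 260 gene list tests, 111 were called with the preset correlation, 5 with an estimated correlation and 213 with fry, which asks another question. Whether replicate numbers mark pairs stayed open: 4 of 18 same-number pairs correlated above 0.1, but 9 of 12 arrays matched best an array of their own number. As a block, replicate numbers gave 8827, 3365, 8927 and 11806 for the regions and 16580 among regions. Gad2 in whole brain against the reference reversed from -0.28 to 0.20 with median centring (not called) and to 0.55 with the mean of probes, whose other probe has the opposite sign, and lost its call at -0.17 with scaling between arrays. Of 251 named results, 5 changed their call or direction under at least 1 alternative. Many of these were named for large differences shown on every array. Calls were less stable than counts. The 2-fold threshold aside, 3072 of 8128 calls held under all alternatives in olfactory bulb and 488 of 2858 in cortex. In striatum 1948 of 8243 held, in cerebellum 2754 of 11051 and in whole brain against the regions 7929 of 16860. Among 2-fold calls, 161 of 164, 38 of 42, 74 of 92, 281 of 319 and 2318 of 2673 held, in that order. Dim signal over background limits small differences. The scan block was not run.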

Other observations

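The counts over other splits of the arrays were planned before the data were examined, and no test in this part was chosen after the results were seen.

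Axon guidance and migration genes had 3 of 25 higher and 12 lower in olfactory bulb (camera adjusted p = 0.0272; adjusted p = 0.182 with an estimated correlation), with Robo2, a guidance receptor, at 1.40 ± 0.08, Efnb2 at 1.38 ± 0.11 and Efna5 at -1.32 ± 0.08, both ephrins. In cerebellum 9 were higher and 9 lower (camera adjusted p = 0.903, direction lower, against a median of 0.03), with the receptors Unc5c at 1.83 ± 0.12, Robo3 at 1.79 ± 0.12 and Plxna4 at -1.91 ± 0.09. Neuropeptide genes had 0 of 14 higher and 6 lower in olfactory bulb (camera adjusted p = 0.00438; adjusted p = 0.0764 with an estimated correlation), with Pnoc, encoding nociceptin, at -1.30 ± 0.14. In whole brain against the reference, caudal ganglionic eminence interneuron genes had 3 of 8 higher and 4 lower (camera adjusted p = 0.281), with Nr2f1 at -4.01 ± 0.07 and Adarb2 at 1.38 ± 0.08. Erythroid genes had 3 of 7 higher and 1 lower (camera adjusted p = 0.787; median 0.11, mean -0.11), with the globins Hbb-y at 0.44 ± 0.07 and Hba-a1 at -2.16 ± 0.10, and sex-linked genes 2 of 5 higher and 2 lower, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.975). Other counts adjusted over the list alone were the same.

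Of 100 splits of the arrays into groups of the same sizes, 1, the real one, called as many genes in each of 6 comparisons. This is the lowest share that 100 splits can give. It bears on the grouping of the arrays alone, not on preparation or scan. The real and the highest other counts were 15693 and 4562 among regions, 8128 and 51 for olfactory bulb, 2858 and 97 for cortex, 8243 and 7682 for striatum, 11051 and 7215 for cerebellum, and 16860 and 5608 for whole brain against the regions. The highest other splits for striatum and cerebellum kept the 3 cerebellar arrays together, and that for whole brain kept 3 whole-brain arrays with 1 cerebellar array.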
